A study of Mus musculus with 12 samples.

How the data were processed

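RNA from uterine tissue of pregnant mice was sequenced at 13.5 days post coitum in 12 libraries, 4 from each of 3 groups. Control mice carried the Myh11Cre driver alone, and the other mice overexpressed progesterone receptor isoform A (PGR-A OE) or isoform B (PGR-B OE) in the myometrium, the smooth muscle layer of the uterus. Per the labels' protocols, tissue was homogenized in Trizol, RNA was purified on columns, libraries were made with a TruSeq RNA kit and reads were paired-end of 75 bp. The titles of the samples gave each library its group and its replicate number. The labels do not say that the replicates of a group came from separate animals, so every p-value measures the spread between these samples, part of which may be technical.

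The authors deposited 1 table of whole-number read counts per gene, not normalized, for all 12 libraries. Per the submitters' processing notes, Bowtie2 2.2.5, STAR 2.7.0f, featureCounts, Subread 1.6.4 and DESeq2 were used, with the builds mm10 and GRCm38. The role of each tool, the gene annotation, the handling of reads that fit several genes and the use of strand are not given in the sources used here. Counts of a gene that overlaps another gene, or that has a near-identical paralog, are therefore uncertain. Genes named by the rule below are said to be uncertain where an overlap or a paralog was found; other genes named were not examined for this. The counts are per gene, so they separate neither the receptor isoforms nor transgene transcripts from endogenous Pgr transcripts.

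The table held 24964 genes, of which 4393 had no count in any library. Total counts ran from 31872534 to 33078483 per library. Chromosome, start and end were taken from the GENCODE annotation of GRCm38 by exact gene symbol for 24379 genes, and overlapping gene models were found with bedtools 2.31.1. Positions are those of the whole annotated gene, from its first to its last exon.

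Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with edgeR's filterByExpr on the 3 groups, which left 15561 genes tested. Libraries were scaled by the trimmed mean of M-values (TMM), and all 12 libraries entered 1 robust quasi-likelihood fit, so that the groups share an estimate of the spread. PGR-A OE against control, PGR-B OE against control and PGR-B OE against PGR-A OE were tested with edgeR's quasi-likelihood test, and p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Levels are given in edgeR's CPM unit, from the TMM-scaled library sizes, as mean ± SD over the 4 libraries of a group. Pgr was also compared by an exact two-sided permutation test of log2 CPM. Where a group had no count of a gene, the fold was computed against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with an exact 95% interval. Such floors and intervals cover counting error only.

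Before the data were examined, the tests, the samples in each fit, 33 gene lists of pathways and cell types, the alternatives and the rule for naming genes were fixed. The rule named, among others, Pgr, Oxtr, Plcl2, Gja1, Ptgs2, Zeb1 and Zeb2 in every comparison. It added, of the genes past the threshold with a mean of at least 1 CPM over the 8 libraries compared and no overlap between the groups, the 10 with the largest rise and the 10 with the largest fall. Gene models without a name were only counted, and if fewer than 3 genes passed in a direction, the 3 with the lowest p would be given as values that did not pass. Up to 4 members with the lowest p were named from each list described. Results for some genes that the rule names are not reported here, though they are included in the counts. Genes outside this rule are said to have been chosen after their values were seen.

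Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, on voom log2 values, adjusted over the lists of a comparison. Camera compares a list with the other genes. It was repeated with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance in 1 direction, was run beside it, as was its test of change in either direction. In PGR-A OE against control the estimate was 0.63 for smooth muscle markers and 0.55 for the interferon response. The preset treats such members as nearly independent, so its p-values are too small for them. The median of a list is over the voom differences of its members. Each count of members past the threshold is given over all genes tested and adjusted over the list alone. Counts of members at an unadjusted p under 0.05 by edgeR must be read beside those over all 15561 genes tested. These were 2400 in PGR-A OE against control, 1444 in PGR-B OE against control and 1251 in PGR-B OE against PGR-A OE.

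Libraries of a group were checked pair by pair for identical counts and for differences within sampling noise, and no pair was found to be the same library deposited under 2 names. The alternatives were relative log expression (RLE) size factors, library size alone, upper quartile factors, no filter on low counts, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma voom with sample quality weights, a fit of the 8 libraries compared, the replicate number as a block, and each library left out in turn. Fits without PGR-A OE replicate 4, alone or with control replicate 4, were added after seeing the data. The overlap of calls between both overexpression groups was set beside 50 simulations of unchanged groups that share the controls and beside the 6 ways of splitting the controls.

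The fits were tested on simulated data, with counts drawn for the real genes from the real means and library sizes and 100 genes changed at each of 2 fold sizes. For PGR-A OE against control, with 15482 genes in the step, edgeR recovered 45% of genes changed 1.5-fold and 68% of those changed 2-fold, and called 4 unchanged genes. For PGR-B OE against control, with 15473 genes, it recovered 34% and 70% and called 4 unchanged genes. For PGR-B OE against PGR-A OE, with 15475 genes, it recovered 45% and 67% and again called 4. DESeq2, with 15561 genes in the step, called 37, 33 and 26 unchanged genes in the same order. Changes under 2-fold were therefore often missed at 4 libraries per group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.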

Results

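Uterine tissue of pregnant mice was profiled by RNA sequencing in 12 libraries, 4 control, 4 PGR-A OE and 4 PGR-B OE libraries. The libraries held between 31872534 and 33078483 counts each, so depth differed little between groups. PGR-A OE replicate 4 lay apart from the other 11 libraries, at 62.4 on the first principal component, which held 23.0% of the variance. The decidual prolactin Prl8a2 was at 5.02 CPM in that library and between 173.6 and 5054 CPM in the other 11, and control replicate 4 held the highest value.

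The gene for the progesterone receptor, Pgr (chromosome 9, 8899833 to 8968611), was higher in both overexpression groups, which is the first check of the labels. Control libraries held 121 ± 16.5 CPM (SD, n = 4), PGR-A OE libraries 199.7 ± 38.5 CPM and PGR-B OE libraries 223 ± 26.5 CPM, and neither overexpression group overlapped the controls. Pgr rose by 0.72 on the log2 scale in PGR-A OE (SE 0.14, adjusted p = 0.0416) and by 0.88 in PGR-B OE (SE 0.14, adjusted p = 0.0196), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The difference between the overexpression groups did not pass (0.16, SE 0.14, adjusted p = 0.821). It was 0.0800 without PGR-A OE replicate 1, 0.104 without PGR-B OE replicate 1 and 0.299 without PGR-A OE replicate 4. The exact two-sided permutation test gave p = 0.0286 for either group against control, the smallest p that 4 against 4 libraries allow, and p = 0.371 between the overexpression groups. Most fits that left out a library lost the call. In PGR-A OE it was kept without PGR-A OE replicate 1 (adjusted p = 0.0475), and in PGR-B OE without control replicate 1 (adjusted p = 0.0327) or PGR-B OE replicate 4 (adjusted p = 0.0232). For PGR-A OE the adjusted p was 0.0587, 0.127, 0.0958 and 0.0824 without control replicates 1, 2, 3 and 4, and 0.0791, 0.0705 and 0.0608 without PGR-A OE replicates 2, 3 and 4. For PGR-B OE it was 0.0698, 0.0784 and 0.0539 without control replicates 2, 3 and 4, and 0.0732, 0.0553 and 0.0533 without PGR-B OE replicates 1, 2 and 3, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was also 0.0902 for PGR-A OE in a fit of the 8 libraries compared. The log2 change stayed between 0.58 and 0.81 in PGR-A OE and between 0.82 and 0.97 in PGR-B OE when libraries were left out.

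**Figure D1:**
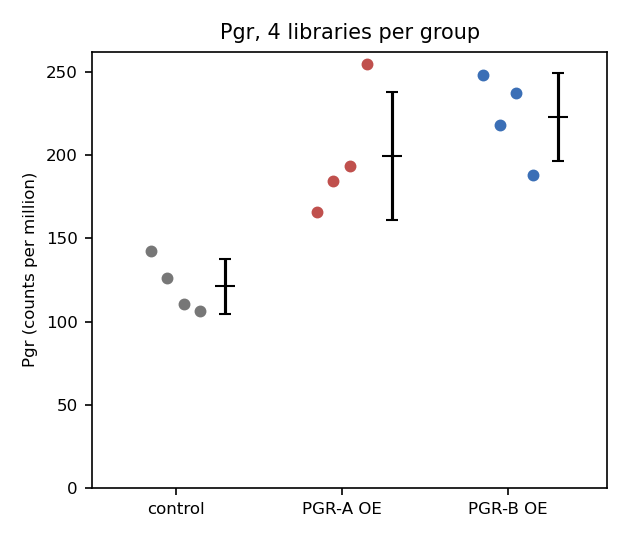
Pgr in CPM (vertical axis) for each library of the control, PGR-A OE and PGR-B OE groups. Points are libraries and the black marks are the mean ± SD (n = 4); the highest control library, at 142 CPM, lies below the lowest PGR-A OE library, at 166 CPM, and the lowest PGR-B OE library, at 188 CPM.

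The first comparison asked which genes differ when isoform A is overexpressed in the myometrium. Hhatl (chromosome 9, 121784016 to 121792507), which encodes a relative of hedgehog acyltransferase, rose from 0.503 ± 0.186 CPM in control to 17.6 ± 4.05 CPM in PGR-A OE (SD, n = 4), a 34.7-fold rise. Casq2 (chromosome 3, 102086415 to 102146514), which encodes a calcium-binding protein of the sarcoplasmic reticulum, rose 4.16-fold from 21.0 ± 7.92 to 87.4 ± 18.0 CPM. P2rx2 (chromosome 5, 110339812 to 110343212), a subunit of an ATP-gated channel, fell from 36.7 ± 7.04 to 19.9 ± 2.65 CPM, and Lrat (chromosome 3, 82892579 to 82903973), the enzyme that esterifies retinol, fell from 197.5 ± 32.8 to 90.5 ± 21.9 CPM. Within the cluster of alpha-1-antitrypsin genes on chromosome 12, Serpina1b and Serpina1c rose while Serpina1e fell.

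Hhatl had a log2 change of 5.12 (SE 0.27, adjusted p = 2.27e-06) and Casq2 of 2.06 (SE 0.23, adjusted p = 0.0019), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Further rises were AI593442 (3.27), Rab3c, a small GTPase of vesicle release (2.97), Vat1l (2.86), the sodium-activated potassium channel gene Kcnt1 (2.78), the secretin receptor gene Sctr (2.31) and Wfdc6a (2.09), and each of these calls was kept in all 8 fits that left out a library. Wfdc6a has a close paralog, Wfdc6b, and reads may be split between them. The falls included Aldh1a7 (-1.97), the cytokine receptor gene Il5ra (-1.05), Lcorl (-1.02), P2rx2 (-0.88, SE 0.15, adjusted p = 0.0219), Gstm5 (-0.76), Stat5a (-0.65), Cpeb2 (-0.58) and Lrat (-1.13, SE 0.19, adjusted p = 0.0235). Lcorl, Gstm5, Stat5a and Cpeb2 overlap other gene models and Aldh1a7 has the paralog Aldh1a1, so their counts are uncertain. Gstm5 kept its call in all 8 fits. Of the other falls named here, Stat5a kept its call in 6 and Aldh1a7 in 5. Serpina1e, Lrat and Lcorl kept it in 3, P2rx2 in 2, Cpeb2 in 1 and Il5ra in 0. The highest adjusted p reached 0.0714 for Aldh1a7, 0.104 for Serpina1e, 0.0943 for Lrat, 0.185 for Il5ra, 0.0767 for Lcorl, 0.0935 for P2rx2, 0.083 for Stat5a and 0.137 for Cpeb2. Of the 21 named calls, 10 ended without control replicate 1, 8 without control replicate 2, 6 without control replicate 3 and 4 without control replicate 4. Without PGR-A OE replicates 1, 2, 3 and 4, the number ended was 7, 10, 6 and 5.

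Serpina1c (chromosome 12, 103894926 to 103904887) had no count in control and 394 counts over the 4 PGR-A OE libraries, which is at least 126-fold higher against a floor of 3 counts over the group. Serpina1b (chromosome 12, 103728156 to 103830373) was at 0.0626 ± 0.0516 CPM in control and 2.33 ± 0.832 CPM in PGR-A OE (SD, n = 4), a log2 change of 5.14 (SE 0.65, adjusted p = 0.00406 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Serpina1e (chromosome 12, 103946931 to 103958975) was far more abundant and fell by 1.16 on the log2 scale (SE 0.20, adjusted p = 0.0256), from 1209.95 ± 279 to 542 ± 131 CPM. These genes are near-identical paralogs, so their separate counts are uncertain.

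Of the lists, smooth muscle markers were higher in PGR-A OE, with 19 of 20 members positive and a median log2 difference of 0.26 (camera adjusted p = 9.03e-07; adjusted p = 0.729 with an estimated correlation). By edgeR 0 members passed over all genes tested (7 at an unadjusted p under 0.05), where DESeq2 called 4 and limma voom 3 higher. Adjusted over the list alone, 5 rose: Synm, Des, Myh11, Hspb8 and Tpm1. The rule names up to 4, so naming all 5 was chosen after their values were seen. Synm, a muscle intermediate filament gene, was at 121 ± 24.2 CPM in control and 206 ± 42.8 CPM in PGR-A OE (0.77, adjusted p = 0.0729 over all genes), and Des at 2119 ± 352 and 3053 ± 189 CPM (0.53, adjusted p = 0.113), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The smooth muscle marker mean of PGR-A OE replicate 4 was 9.38 log2 CPM, above the 8.86 to 9.05 of the other 3 PGR-A OE libraries, and the list's median was 0.17 without that library.

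The interferon response was higher in all 17 members tested, with a median of 0.46 (camera adjusted p = 9.03e-07; adjusted p = 0.672 with an estimated correlation). By edgeR 0 members passed over all genes (10 at an unadjusted p under 0.05), where DESeq2 called 3 and limma voom 7 higher. Adjusted over the list alone, 6 rose. Among them, Ifi44 was at 20.6 ± 4.06 CPM in control and 35.01 ± 9.44 CPM in PGR-A OE (0.77), Ifit3 at 20.4 ± 4.70 and 33.7 ± 5.86 CPM (0.72), and Oas2 at 37.2 ± 5.55 and 51.1 ± 3.05 CPM (0.46; SD, n = 4). Here PGR-A OE replicate 4, at a list mean of 4.90 log2 CPM, lay below the 5.17 to 5.44 of the other 3 libraries of its group and beside the highest control, at 4.89.

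Extracellular matrix genes were higher in 21 of 26 members (median 0.23, camera adjusted p = 6.04e-05; adjusted p = 0.672 with an estimated correlation). Col14a1, a collagen gene, rose from 215.9 ± 9.54 to 304 ± 26.2 CPM (0.49, adjusted p = 0.0417 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), the 1 member past the threshold both over all genes and adjusted over the list alone. DESeq2 called 4 members higher, and limma voom 6 higher and 1 lower. The Col14a1 call remained in 1 of 8 fits that left out a library, with adjusted p up to 0.156. By fry, change in either direction over the extracellular matrix list gave an adjusted p of 0.0013. Endothelial markers were higher in all 13 members (median 0.20, camera adjusted p = 0.000308; adjusted p = 0.672 with an estimated correlation), with 1 past the threshold adjusted over the list alone, Vwf, the von Willebrand factor gene, at 37.7 ± 3.55 CPM in control and 58.6 ± 14.6 CPM in PGR-A OE. Over all genes DESeq2 called 1 and limma voom 3 endothelial markers higher. In fibroblast markers 8 of 10 members were positive (median 0.23, camera adjusted p = 0.0224; adjusted p = 0.672 with an estimated correlation), and Col15a1 rose from 494 ± 41.4 to 920.1 ± 246 CPM (0.90, adjusted p = 0.0392). Adjusted over the list alone, 2 fibroblast markers rose, and DESeq2 and limma voom each called 2 higher over all genes. By fry, change in either direction gave an adjusted p of 0.0232, and 0.117, 0.2 and 0.145 without control replicates 1, 2 and 4. The fibroblast list did not pass without control replicate 4 (adjusted p = 0.133) or PGR-A OE replicate 4 (adjusted p = 0.151), and Col15a1 passed in 2 of 8 fits that left out a library, with adjusted p up to 0.146. PGR-A OE replicate 4 had the highest fibroblast mean, 8.48 log2 CPM against 8.005 to 8.07 in the other 3 libraries of its group.

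Genes of the unfolded protein response were lower, with 2 of 18 members positive and a median of -0.13 (camera adjusted p = 0.0224; adjusted p = 0.854 with an estimated correlation). By edgeR 0 members passed over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05), and 0 by DESeq2 or limma voom. The lowest p belonged to Edem1 (-0.19), Manf (-0.31) and Dnajb9 (-0.50). The list's call rested on PGR-A OE replicate 4, whose list mean was 6.60 log2 CPM against 6.9993 to 7.15 in the other 3 libraries, since adjusted p was 0.66 without it, with a median of -0.05, and 0.133 without control replicate 4.

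**Figure D2:**
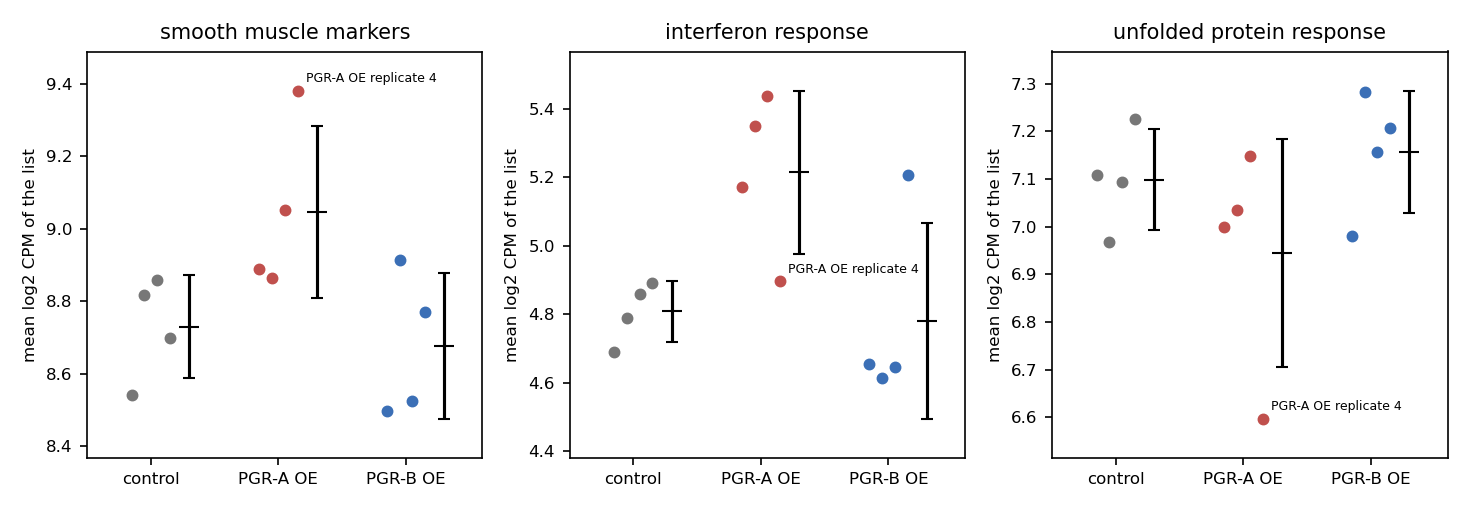
Mean log2 CPM (vertical axis) over the smooth muscle, interferon response and unfolded protein response lists, for each library of the control, PGR-A OE and PGR-B OE groups. Points are libraries, black marks are the mean ± SD (n = 4), and the named point is PGR-A OE replicate 4, highest of the 12 for smooth muscle (9.38) and lowest for the unfolded protein response (6.60); the axes do not start at 0.

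In all, 102 genes passed in PGR-A OE against control, 75 higher and 27 lower, of 15561 genes tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At least 2-fold changes made up 33 of the rises and 6 of the falls. Before adjustment, 2400 of the 15561 genes had a p under 0.05 by that test. The 8 libraries did not overlap in any of the 102 genes; of all genes tested, 10.6% showed no overlap, where chance gives 2.86%. The count was 32 without control replicate 1, 43 without control replicate 2, 44 without PGR-A OE replicate 1 and 56 without PGR-A OE replicate 2, and 96 without PGR-A OE replicate 4 and control replicate 4 together. It was 63 in a fit of the 8 libraries compared. The balance differed between tools, with 293 higher and 282 lower of 575 genes by DESeq2, and 465 higher and 580 lower of 1045 by limma voom; DESeq2 called 100 of the 102 genes and limma voom 102. Of the genes fixed for their place in uterine contraction or progesterone action, Oxtr, Plcl2, Gja1, Ptgs2, Zeb1 and Zeb2 did not pass, with adjusted p from 0.574 for Zeb1 to 0.992 for Zeb2. Zeb1 and Zeb2 overlap other gene models, so their counts are uncertain in each comparison. The oxytocin receptor gene Oxtr was at 14.1 CPM in PGR-A OE replicate 4 and between 3.37 and 4.84 CPM in the other 3 libraries of the group, against 7.84 ± 1.41 CPM in control. Its log2 change of -0.23 became -0.90 without PGR-A OE replicate 4. Over the 8 fits that left out a library its adjusted p by edgeR's quasi-likelihood test was 0.0873 at the lowest. The phospholipase C and Gq signalling list (0 of 35 members past the threshold by edgeR, 0 adjusted over the list alone, 5 at an unadjusted p under 0.05, 0 by DESeq2 and 1 lower by limma voom) and the contraction-associated list (0 of 14, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2 or limma voom) did not pass either.

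The second comparison asked the same for isoform B, which the series title ties to the phospholipase C pathway and to uterine contractility. Hhatl rose 25.96-fold, to 13.1 ± 2.604 CPM (SD, n = 4). Ptn (chromosome 6, 36714929 to 36810220), which encodes the secreted growth factor pleiotrophin, rose 4.64-fold from 212 ± 41.7 to 983 ± 71.5 CPM. Calb2 (chromosome 8, 110137502 to 110168210), the calretinin gene, rose from 0.362 ± 0.151 to 5.56 ± 2.49 CPM. P2rx2 fell from 36.7 ± 7.04 to 15.8 ± 2.34 CPM. Fkbp5 (chromosome 17, 28399094 to 28517527), a co-chaperone of steroid receptors and a known progesterone target, rose from 69.1 ± 9.14 to 132 ± 23.5 CPM.

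The log2 changes were 4.70 for Hhatl (SE 0.27, adjusted p = 5.78e-06), 2.21 for Ptn (SE 0.20, adjusted p = 0.000497), 3.93 for Calb2 (SE 0.45, adjusted p = 0.00259) and -1.21 for P2rx2 (SE 0.15, adjusted p = 0.00462), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Sctr (2.72), Mum1l1 (2.701) and Asic4, of the acid-sensing channel family (2.44), rose as well, and these 7 calls were kept in all 8 fits that left out a library. Slc26a1, an anion transporter gene (2.53), AI593442 (2.47), Vwce (2.45) and Rab3c (2.37) rose too, though their adjusted p reached 0.0741, 0.095, 0.0503 and 0.0516 in such fits. Slc26a1 and Vwce overlap other gene models, which leaves their counts uncertain. The other falls were Adamts3 (-0.55), Chst11 (-0.47) and Mbnl2 (-0.43). In such fits their adjusted p by edgeR ran from 0.0406 to 0.148, from 0.0697 to 0.166 and from 0.051 to 0.152. Chst11 and Mbnl2 thus lost their call in each of the 8 fits. Of the 15 named calls, 6, 8, 5 and 4 ended without control replicates 1, 2, 3 and 4, and 4, 5, 4 and 5 without PGR-B OE replicates 1, 2, 3 and 4.

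**Figure D3:**
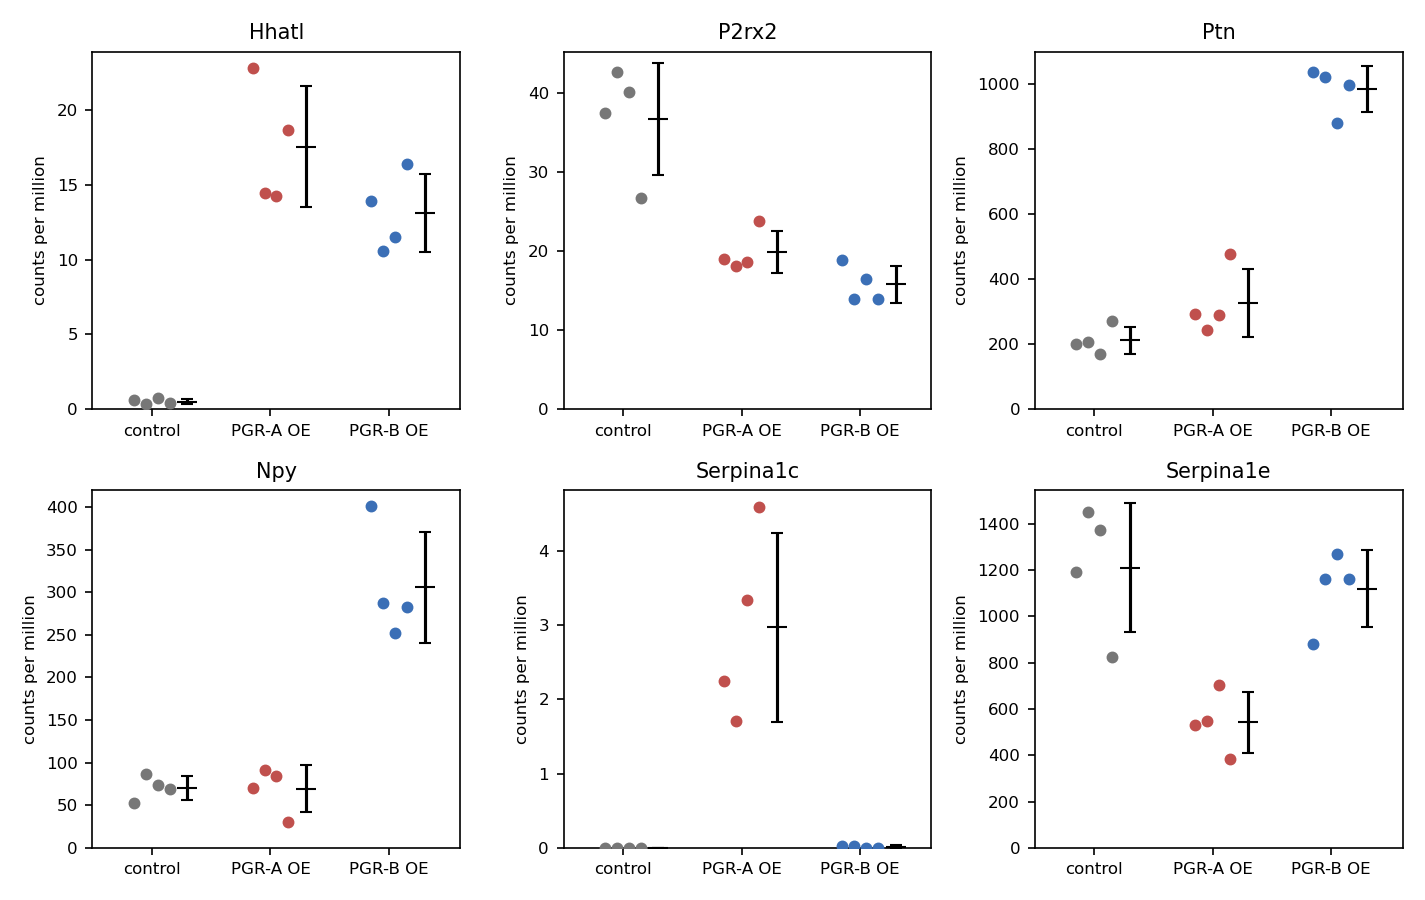
CPM (vertical axes, from 0) of 6 genes, Hhatl, P2rx2, Ptn, Npy, Serpina1c and Serpina1e, for each library of the control, PGR-A OE and PGR-B OE groups. Points are libraries and black marks are the mean ± SD (n = 4); Hhatl was at most 0.726 CPM in control and at least 10.6 CPM in the other groups, and Serpina1c was at 0 in every control library and at least 1.71 CPM in PGR-A OE.

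In the list of progesterone-responsive genes, Fkbp5 was the 1 of 25 members past the threshold, both over all genes (0.94, SE 0.13, adjusted p = 0.00743 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and adjusted over the list alone. Hoxa11 (0.62) and Hand2 (0.56), transcription factors of the uterus, did not pass, and were at 0.41 and 0.30 without PGR-B OE replicate 1. In that library the mean of this list was 5.09 log2 CPM, against 4.67 to 4.71 in the other 3 libraries. In the phospholipase C and Gq signalling list, 0 of 35 members passed over all genes by edgeR, 7 had an unadjusted p under 0.05, and 2 rose and 1 fell when adjusted over the list alone. Of all 15561 genes tested, 1444 had an unadjusted p under 0.05 by edgeR. DESeq2 called 1 member lower, and limma voom 1 higher and 1 lower. The inactive phospholipase C relative Plcl2 (chromosome 17, 50509403 to 50688484) was at 34.0 ± 5.98 CPM in control and 49.2 ± 2.56 CPM in PGR-B OE, with no overlap (0.53, SE 0.15, adjusted p = 0.242 over all genes). Prkcb, a protein kinase C gene, was at 47.1 ± 6.996 and 61.1 ± 4.11 CPM (0.38, adjusted p = 0.243). Plcd4, a phospholipase C gene, was at 2.82 ± 0.552 CPM in control and 1.55 ± 0.114 CPM in PGR-B OE (-0.86, adjusted p = 0.0887). The list did not pass by camera (adjusted p = 0.866) or in 1 direction by fry (adjusted p = 0.965). It passed fry's test of change in either direction (adjusted p = 0.0318), a call lost without control replicates 1, 2 and 3 (adjusted p = 0.302, 0.0565 and 0.5) and without PGR-B OE replicates 1 and 4 (adjusted p = 0.293 and 0.322). Among calcium channels and pumps, 0 of 18 passed over all genes by edgeR (3 at an unadjusted p under 0.05) and by limma voom, and 1 higher and 1 lower by DESeq2, while the store sensor gene Stim1 (0.34) rose and the channel gene Cacna1h (-0.37) fell adjusted over the list alone. In the contraction-associated list 0 of 14 passed on either count by edgeR or over all genes by DESeq2 or limma voom, and 1 had an unadjusted p under 0.05.

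Oxtr was at 5.02 ± 1.01 CPM in PGR-B OE and 7.84 ± 1.41 CPM in control (-0.64, SE 0.38, adjusted p = 0.639 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its libraries ran from 3.92 to 6.25 CPM in PGR-B OE and from 6.22 to 9.66 CPM in control. The spread is shared by all groups, so PGR-A OE replicate 4, at 14.1 CPM, enters this SE. The p-value therefore does not show that Oxtr was unchanged. Gja1, Ptgs2, Zeb1 and Zeb2 did not pass either, with adjusted p from 0.575 for Ptgs2 to 0.993 for Zeb1. Among smooth muscle markers 7 of 20 members were positive and among the interferon response 8 of 17, and neither list passed (camera adjusted p = 0.53 and 0.866). In the extracellular matrix list, 0 of 26 passed over all genes by edgeR (9 at an unadjusted p under 0.05), DESeq2 called 4 higher and 1 lower and limma voom 4 higher. Adjusted over the list alone, 4 rose and 1 fell, among them Col1a1 (0.45) and the fibronectin gene Fn1 (-0.84); camera gave an adjusted p of 0.189 and fry, for change in either direction, an adjusted p of 0.000689. Cholesterol synthesis was the 1 list that passed, with 1 of 20 members positive and a median of -0.18 (camera adjusted p = 0.00859; adjusted p = 0.927 with an estimated correlation). By edgeR 0 of its members passed over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05), and 0 by DESeq2 or limma voom. Sc5d, a sterol desaturase gene, had the lowest p (-0.34, adjusted p = 0.397). The list's call rested on control replicate 4, whose list mean was 5.71 log2 CPM against 5.20 to 5.29 in the other 3 controls, since the adjusted p was 0.531 and the median -0.04 without it.

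Over all 15561 genes, 48 passed in PGR-B OE against control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 44 higher and 4 lower, with 27 rises and 1 fall of at least 2-fold. None of the 48 overlapped between groups; 5.67% of all genes tested did not overlap, where chance gives 2.86%. The count was 22 without control replicate 2, 24 without control replicate 1 and 28 without PGR-B OE replicate 4. It was 100 when PGR-A OE replicate 4 was left out of the shared spread, and 91 when control replicate 4 was left out too. DESeq2 called 216 genes, 143 higher and 73 lower, and limma voom 156, 104 higher and 52 lower, each including all 48. The share of falls was larger with these tools.

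The calls of both comparisons shared 27 genes in the same direction, 25 higher and 2 lower, and 0 in opposite directions. They included Hhatl, AI593442, Rab3c, Sctr, Wfdc6a, Asic4 and Pgr among the rises, and P2rx2 and Chst11 as the falls. Chst11 lost its call in PGR-B OE in each fit that left out a library of that comparison. None of the 27 differed between the overexpression groups by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p from 0.195 to 0.977. Independent lists of these sizes would share 0.212 higher and 0.00694 lower genes, and 50 simulations of unchanged groups sharing the controls gave 0 at the median and 0 at most. Unchanged groups yield few calls, so these simulations cannot show how many of the 27 genes come from the shared controls. Part of the overlap may come from the shared controls, since with the controls split between the comparisons the shared genes numbered 2 at the median, from 1 to 5 over 6 assignments. The split fits also called fewer genes, 8 to 69 for PGR-A OE and 10 to 17 for PGR-B OE. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.518, while unchanged groups sharing the controls gave 0.495 at the median and 0.534 at most. The covariance was 0.0697 against 0.0322 simulated, a difference of 0.0376. With the controls split between the comparisons, r was 0.165 at the median, from 0.0567 to 0.221 over the 6 assignments. The shared count was 5 without control replicate 1, 7 without control replicate 2, 14 without PGR-A OE replicate 1, 15 without PGR-B OE replicate 4 and 16 without PGR-A OE replicate 2 or 3. Without PGR-A OE replicate 4 it was 36, with 1 further gene in opposite directions.

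The third comparison set the overexpression groups against each other, and is the test of whether a change from control differs between them. Ptn was 3.02-fold higher in PGR-B OE than in PGR-A OE, at 983 ± 71.5 against 326 ± 104 CPM (SD, n = 4). Npy (chromosome 6, 49822710 to 49829507), the neuropeptide Y gene, was 4.41-fold higher, at 306 ± 65.3 against 69.3 ± 27.6 CPM, and control was at 70.8 ± 14.1 CPM. Mum1l1 (chromosome X, 139210042 to 139238335) was at 15.1 ± 5.19 against 2.31 ± 0.832 CPM. Aldh1b1 (chromosome 4, 45799022 to 45804604), a mitochondrial aldehyde dehydrogenase gene, was lower in PGR-B OE, at 35.1 ± 2.55 against 70.8 ± 10.9 CPM, with control at 31.0 ± 2.65 CPM. Serpina1b and Serpina1c were lower in PGR-B OE, where they were near the control level.

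The log2 differences were 1.59 for Ptn (SE 0.20, adjusted p = 0.00487), 2.14 for Npy (SE 0.29, adjusted p = 0.0126), 2.702 for Mum1l1 (SE 0.29, adjusted p = 0.00204) and -1.01 for Aldh1b1 (SE 0.11, adjusted p = 0.00204), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Aldh1a7 (2.91) and L3mbtl4 (1.66) were also higher in PGR-B OE, and Serpina1b (-5.33) lower. For Serpina1c, 2 counts in PGR-B OE stood against 394 in PGR-A OE, a ratio of 0.00523 (exact 95% interval 0.000631 to 0.0190). These calls were kept in all 8 fits that left out a library, except Npy, at adjusted p up to 0.0652. Aldh1a1, which makes retinoic acid, was higher (0.62), and Pgbd5 (-1.22), Nipal4 (-1.08), the semaphorin receptor gene Nrp2 (-0.72) and the RNA editing gene Adarb1 (-0.60) were lower. Those 5 calls were lost in 6 or more of the 8 fits, and that of Aldh1a1 in all 8. Their adjusted p reached 0.136, 0.136, 0.136, 0.141 and 0.136. Of the 13 named calls, 6, 5, 5 and 3 ended without PGR-A OE replicates 1, 2, 3 and 4, and 6, 4, 4 and 3 without PGR-B OE replicates 1, 2, 3 and 4. Aldh1a1 and Aldh1a7 are paralogs, as are the Serpina1 genes, and their counts are uncertain.

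Smooth muscle markers were lower in PGR-B OE than in PGR-A OE in all 20 members, with a median of -0.34. Camera gave an adjusted p of 2.56e-12 at the preset correlation and 0.65 at the estimated correlation of 0.63. Fry in 1 direction gave an adjusted p of 0.38. By edgeR 0 members passed over all genes (11 at an unadjusted p under 0.05), where DESeq2 called 2 lower, Synm and Des, and limma voom 0. Adjusted over the list alone, 8 fell, among them Synm (-0.77), Des (-0.61), Tpm1 (-0.50) and Actg2 (-0.51). Interferon response genes were lower in all 17 members (median -0.43, camera adjusted p = 7.7e-11; adjusted p = 0.65 with an estimated correlation), with 5 lower adjusted over the list alone, such as Ifi44 (-0.91) and Usp18 (-0.69). Over all genes edgeR and limma voom called 0 of them (7 at an unadjusted p under 0.05 by edgeR) and DESeq2 called 1, Ifi44. PGR-B OE replicate 4 was at an interferon list mean of 5.21 log2 CPM and the other 3 PGR-B OE libraries between 4.61 and 4.66. Endothelial markers were lower in all 13 members (median -0.18, camera adjusted p = 0.000645; adjusted p = 0.65 with an estimated correlation), and 0 passed on either count by edgeR (2 at an unadjusted p under 0.05) or over all genes by DESeq2 or limma voom. The median was -0.12 without PGR-B OE replicate 2. The smooth muscle mean of PGR-A OE replicate 4, given above, was the highest of all 12 libraries. This list and the interferon list passed by camera at the preset correlation in all 8 fits that left out a library. The same PGR-A OE libraries gave the rises of both lists against control, and neither list passed in PGR-B OE against control.

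Genes of the unfolded protein response were higher in 17 of 18 members (median 0.19, camera adjusted p = 9.33e-05; adjusted p = 0.684 with an estimated correlation), with 0 past the threshold on either count by edgeR (4 at an unadjusted p under 0.05); Creld2 (0.44) had the lowest p. Without PGR-A OE replicate 4 the median was 0.10 and the adjusted p 0.0634. Extracellular matrix genes were lower, with 7 of 26 members positive (median -0.12, camera adjusted p = 0.00753; adjusted p = 0.684 with an estimated correlation), with 0 past on either count by edgeR (5 at an unadjusted p under 0.05). The adjusted p was 0.0735 without PGR-B OE replicate 1 and 0.0926 without PGR-B OE replicate 3, with a median of -0.0749, and the median was -0.19 without PGR-A OE replicate 4. The relaxation and potassium channel list was lower, with 4 of 20 members positive (median -0.12, camera adjusted p = 0.0312; adjusted p = 0.684 with an estimated correlation), with 0 past on either count by edgeR (2 at an unadjusted p under 0.05); Kcnma1, a calcium-activated potassium channel gene, was at -0.41. Its adjusted p was 0.646 without PGR-A OE replicate 4, with a median of -0.0369, and 0.205 without PGR-B OE replicate 3, with a median of -0.0854. Its median was -0.20 without PGR-A OE replicate 3 and -0.21 without PGR-B OE replicate 1. In these 3 lists DESeq2 and limma voom called 0 members over all genes.

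Phospholipase C and Gq signalling, contraction-associated genes, calcium channels and progesterone-responsive genes did not pass as lists between the isoforms. Of all 15561 genes tested between them, 1251 had an unadjusted p under 0.05 by edgeR. Plcl2 was at 49.2 ± 2.56 CPM in PGR-B OE and 35.6 ± 7.46 CPM in PGR-A OE (0.47, SE 0.15, adjusted p = 0.45 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Adjusted over the list alone, 0 of 35 members of the phospholipase C list passed by edgeR (7 at an unadjusted p under 0.05; over all genes 0 by DESeq2 and 1 higher by limma voom), 1 of 18 calcium channel genes fell (Cacna1h, -0.55, adjusted p = 0.0693 over all genes), and 1 of 25 progesterone-responsive genes rose (Fkbp5, 0.70, adjusted p = 0.0857 over all genes). Over all genes DESeq2 and limma voom each called 1 calcium channel gene lower and 1 progesterone-responsive gene higher. Oxtr, Gja1, Ptgs2, Zeb1 and Zeb2 did not pass, and the Oxtr difference of -0.41 became 0.25 without PGR-A OE replicate 4. In total 18 genes passed between the isoforms, 9 higher and 9 lower, none with overlapping groups; 3.85% of all genes tested did not overlap, where chance gives 2.86%. The count was 11 without PGR-A OE replicate 1, PGR-A OE replicate 2 or PGR-B OE replicate 1, 31 without PGR-A OE replicate 4, 38 without PGR-A OE replicate 4 and control replicate 4 together, 10 in a fit of the 8 libraries compared and 7 with genes of at least 1 CPM. It was 11 with the replicate number as a block, 125 with DESeq2 (43 higher, 82 lower), which called all 18, and 81 with limma voom (48 higher, 33 lower), which called 17 of them.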

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

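The tests of liver genes, of reads shared between Serpina1 genes, and of smooth muscle and decidual markers, depth and summed Serpina1a to Serpina1c in PGR-A OE replicate 4 were chosen only after the result was seen. Of 234 groups of 4 libraries examined by Dixon's test, 19 held a library far from the other 3, where chance gives about 1 in 20. Among named genes, Oxtr was at 14.1 CPM in PGR-A OE replicate 4 (3.37 to 4.84 in the other 3) and P2rx2 at 23.9 CPM in the same library (18.2 to 19.0). Rab3c was at 5.56 CPM in PGR-A OE replicate 1 (3.22 to 3.597) and Calb2 at 9.29 CPM in PGR-B OE replicate 1 (4.07 to 4.48). In control, Aldh1b1 was at 27.0 CPM in replicate 1 (32.1 to 32.5), Il5ra at 48.0 CPM in replicate 2 (35.8 to 37.1) and Wfdc6a at 0.631 CPM in replicate 3 (0.445 to 0.476).

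Among lists, given as mean log2 CPM, PGR-A OE replicate 4 stood apart for calcium channels and pumps (5.31, others 4.93 to 4.98) and fibroblast markers (8.48, others 8.005 to 8.07), and PGR-A OE replicate 2 for immediate early genes (4.90, others 4.56 to 4.61). Control replicate 4 stood apart for hypoxia (5.35, others 4.89 to 4.95), cholesterol synthesis (5.71, others 5.20 to 5.29) and trophoblast markers (-2.01, others -2.84 to -2.78). PGR-B OE replicate 1 stood apart for progesterone-responsive genes (5.09, others 4.67 to 4.71), uterine natural killer cell markers (2.14, others -0.98 to -0.45) and neutrophil markers (-1.49, others -1.07 to -0.99). PGR-B OE replicate 3 stood apart for trophoblast markers (-0.48, others -2.69 to -2.33), and PGR-B OE replicate 4 for the interferon response (5.21, others 4.61 to 4.66) and phospholipase C and Gq signalling (4.42, others 4.47).

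PGR-B OE differed from PGR-A OE, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, for 5 genes that were also named against control. A difference between the groups need not be an effect of the isoform, and the Serpina1 genes are taken up below. The log2 differences were 2.91 for Aldh1a7 (adjusted p = 0.00204), 2.702 for Mum1l1 (adjusted p = 0.00204), 1.59 for Ptn (adjusted p = 0.00487), -5.33 for Serpina1b (adjusted p = 0.00487) and -7.26 for Serpina1c (adjusted p = 0.00204). The value for Serpina1c is a fitted one that rests on 2 counts in PGR-B OE. Of the 35 ways to split the 8 libraries of a comparison into 4 and 4, only the real split called as many genes, in each comparison. That is under 5% of the splits for each comparison, not adjusted over the comparisons. The splits cannot tell overexpression from any other difference between the samples of the groups. The real split called 102 genes in PGR-A OE against control and any other at most 6. It called 48 in PGR-B OE against control and any other at most 26, and 18 between the isoforms and any other at most 1.

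Serpina1b and Serpina1c rose and Serpina1e fell in PGR-A OE. Serpina1a, chosen after its values were seen, rose as well, from 0.0472 ± 0.0187 to 1.85 ± 0.404 CPM (SD, n = 4). RNA from liver would bring other liver transcripts. The 6 liver genes tested of 11 listed had a median log2 change of -0.47 (SD 0.812 over genes, 0 called). They went both ways, with Alb at 0.31, Trf at 0.31 and Apoa2 at 0.19, and Apoa1 at -1.14, Fga at -1.24 and Afp at -1.25. They did not rise together, but a trace of liver RNA too small to move these genes cannot be excluded. Reads moved to the paralogs cannot account for the fall of Serpina1e, since Serpina1a to Serpina1d gained 1.07% of the 668 CPM it lost. That test sees only reads counted at the paralogs, and the handling of reads that fit several genes is not given. Misplaced Serpina1e reads stay open for the rises. Serpina1a to Serpina1c amounted to 1.33% of the Serpina1e counts in PGR-A OE and 0.00910% in control. A sequence variant could change that share. Another haplotype of the cluster in the PGR-A OE mice stays open: of 37 other genes tested within 2 Mb of Serpina1e, 9 had an unadjusted p under 0.05, or 24.3% against 15.5% elsewhere (Fisher exact p = 0.167), and an effect of isoform A on the cluster cannot be told apart from it.

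PGR-A OE replicate 4 lay apart from the other 11 libraries. Its depth, 32214956 counts, lay within the range of the others, which argues against low depth. A control or PGR-B OE library under the wrong label was tested in 2 ways, and the test written before the result was seen went toward that explanation: of 13 genes that separated the other 3 PGR-A OE libraries from both other groups, 6 (46.2%) lay on the PGR-A OE side. These 13 genes were chosen by the other 3 libraries, so a library that lies apart can miss their side whatever its label. The test chosen afterwards went against a wrong label, but with a limit. Serpina1b and Serpina1c were named by a rule that asked for no overlap between the groups, this library included. A level above the controls in this library was therefore a condition of naming them. Summed Serpina1a, Serpina1b and Serpina1c stood at 10.0 CPM in this library and at 4.99 to 7.03 in the other 3 PGR-A OE libraries. In the 8 others the sum was at most 0.351. These 3 genes are also among the 6. A piece of tissue with less decidua and more smooth muscle stays open: smooth muscle markers lay 0.40 above the other 3 libraries on the log2 scale at the median (SD 0.256 over genes) and Prl8a2 was at 5.02 CPM against at least 173.6 CPM elsewhere, but the decidual markers as a set lay at -0.0423 (SD 2.28, 6 of 12 higher).

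Called genes could mark DNA of another strain carried along with a transgene, rather than a response to the receptor. The labels do not say where the transgenes lie. Within 10 Mb of Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077333), a common site for transgenes, lay 1 of 123 called genes, 0.813% against 0.802% of genes tested (Fisher exact p = 1), but the exact 95% bound of 4.45% is too wide to exclude an excess. Elsewhere, 31 called genes lay within 1 Mb of another called gene, against 23 at the median and 33 at the 95th percentile of 10000 random sets (permutation p = 0.0979), which leaves strain DNA open. A response of neighbouring genes to the receptor stays open too, and was not tested.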

How the results depend on the processing

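Fry's test of change in either direction, and the fits without PGR-A OE replicate 4 in the shared spread, and without it and control replicate 4, were chosen only after the data were seen; the other alternatives were planned. Of 1736 alternatives to 95 results for named genes, 1491 kept direction and side of the threshold, 193 lost the call, 32 gained 1 and 20 turned direction. Of 143 alternatives to 13 list calls, 107 kept the call, 36 lost it and 0 turned. Leaving out single libraries of the groups compared gave 32 to 99 calls for PGR-A OE, 22 to 48 for PGR-B OE and 11 to 31 between isoforms. Pgr changes were 0.58 to 0.81 and 0.82 to 0.97. Passing lists numbered 0 to 5 for PGR-B OE. They were 0 without control replicate 4, and 3 and 4 without control replicates 1 and 3. Without PGR-B OE replicates 1, 2, 3 and 4 they were 2, 5, 2 and 2. Between isoforms 6 to 10 lists passed (10 without PGR-B OE replicate 2). Over all 12 libraries left out, 5 to 36 genes were shared. Leaving out a PGR-B OE library gave 72 to 109 calls for PGR-A OE against control. Leaving out a PGR-A OE library gave 33 to 100 calls for PGR-B OE against control. DESeq2 called 575, 216 and 125 genes, with 100 shared, and limma voom 1045, 156 and 81. In the simulated data the share of unchanged genes among the DESeq2 calls was above what the threshold allows. A fit of the 8 libraries called 63 in PGR-A OE and 10 between isoforms, and the 1 CPM filter 7 between isoforms. With both replicates 4 left out, the calls were 96, 91 and 38, and PGR-B OE had 100 without PGR-A OE replicate 4 in the spread. Splitting the controls left 2 shared genes at the median, with fewer controls in each fit. No pairing of the samples by replicate number was detected, since 0 of 12 libraries correlated best with their own number in both other groups. This check cannot exclude a pairing. As a block the replicate numbers gave 69, 32 and 11 calls and 2 passing lists in PGR-B OE. Pgr lost its call in PGR-A OE with 8 libraries (0.72), the block (0.72) and both replicates 4 left out (0.52), and in PGR-B OE with the block (0.88). No list passed with an estimated correlation (0 in each comparison) or by fry in 1 direction (0 in each). In either direction fry passed 2, 2 and 0 lists. Extracellular matrix kept that call in both comparisons with control in each fit without 1 library and with the block. Fibroblast markers lost it without control replicates 1, 2 and 4 (adjusted p = 0.117, 0.2 and 0.145) and with the block (0.053) in PGR-A OE. Phospholipase C and Gq signalling in PGR-B OE lost it in 5 fits, with adjusted p from 2.4e-05 to 0.5 over single libraries left out.

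Values of some uncalled genes turned direction, among them Oxtr (-0.41) and Ptgs2 (0.36) between isoforms; the cause was not tested. With limma voom, Plcl2 was -0.0558 and Zeb2 -0.0566 in PGR-A OE, Zeb1 -0.00894 in PGR-B OE and Gja1 0.0392 between isoforms. With both replicates 4 left out, Zeb2 was -0.16 in PGR-A OE, and Oxtr 0.26, Gja1 0.0299 and Zeb1 0.00167 between isoforms. Over single libraries left out, PGR-A OE gave Plcl2 -0.0602 to 0.16, Gja1 -0.23 to 0.0653 and Zeb2 -0.0789 to 0.0716, PGR-B OE gave Zeb1 -0.0483 to 0.0605, and the isoforms gave Oxtr -0.63 to 0.25, Gja1 -0.19 to 0.0255 and Ptgs2 -0.0298 to 0.68. At this depth and with 4 libraries per group, changes under 2-fold were often missed, as simulated data showed.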

Other observations

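The genes of this part were chosen only after their values were seen, and no explanation is tested here. Slco2a1 (chromosome 9, 102988712 to 103096002), a prostaglandin transporter gene among the 27 shared genes, rose from 39.9 ± 5.55 CPM in control to 75.1 ± 7.60 CPM in PGR-A OE and 131 ± 38.2 CPM in PGR-B OE (SD, n = 4). Pde3b, which encodes an enzyme that breaks down cyclic AMP, rose from 41.2 ± 2.09 to 62.4 ± 11.3 and 66.6 ± 3.405 CPM. The neighbouring collagen genes Col4a3 and Col4a4, 72 bp apart on chromosome 1, rose in both groups, by 1.04 and 0.90 on the log2 scale in PGR-A OE and by 0.99 and 1.24 in PGR-B OE.

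Adcy5, an adenylyl cyclase gene, rose in PGR-A OE from 54.4 ± 6.60 to 85.4 ± 11.9 CPM (0.65, adjusted p = 0.0343 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Ptgis, the prostacyclin synthase gene, from 60.9 ± 10.2 to 97.4 ± 13.3 CPM (0.68, adjusted p = 0.0287). Neither passed in PGR-B OE (0.10 and 0.16) or between the isoforms (-0.55, adjusted p = 0.186, and -0.51, adjusted p = 0.223). Shisa6 rose in PGR-B OE from 0.0929 ± 0.0544 to 1.83 ± 0.284 CPM (4.23, adjusted p = 0.000518) and differed from PGR-A OE (3.51, adjusted p = 0.00204). Ccdc13, whose gene lies 5120 bp from Hhatl, rose in PGR-A OE (2.85, adjusted p = 0.0447) and was at 2.10 in PGR-B OE (adjusted p = 0.252), at levels below 1.06 CPM in each library.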
